A study of Homo sapiens with 4 samples.

How the data were processed

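RNA sequencing of MCF7 cells was analysed in 4 libraries, 2 from cells treated with DMSO and 2 from cells treated with 10 µM Nutlin-3 for 8 h. Groups and replicate numbers came from the sample titles and treatment labels. Per the labels' protocols, total RNA was used to build libraries for paired-end Illumina sequencing. The authors deposited 1 table of TPM values for 37247 Ensembl gene IDs, in which each library sums to 1000000, and the unit follows from its name and its values. Per the submitters' processing notes, the genome build was GRCh38, and DESeq2 is named there with no stated role. The aligner, the counter, the annotation and whether counting used strand are not given in the sources used here. TPM keeps no read depth, so no counting intervals or detection limits were computed, and no count test was used.

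IDs were matched without their version to GENCODE release 29 (GRCh38), which held 34620 of them (92.9%), and symbols came from a table of gene names or from that release. The 2627 IDs without a symbol were kept, and 489 of them had a mean of at least 1 TPM. The table held protein-coding genes and pseudogenes, with 10 long intergenic or antisense RNA IDs, so other noncoding RNAs were not analysed here. Of 19951 protein-coding genes of the release 206 were not analysed here for lack of an ID match. Values in the major histocompatibility complex need care. Between 28 and 34 Mb of chromosome 6, 104 of 160 protein-coding genes (65.0%) had a mean under 1 TPM, against 334 of 841 (39.7%) elsewhere on the chromosome, and HLA-A, HLA-C, HSPA1A and DDX39B, a splicing helicase gene used by all cells, were listed at 0 in all 4 libraries. A 0 in this table therefore need not mean an absent transcript, for a reason that was not tested, and such genes are described as listed at 0.

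The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with empirical Bayes moderation and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the 13692 genes with a mean of at least 1 TPM over the 4 libraries and a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 3.45. Gene lists were compared with all other tested genes by camera in limma with a preset correlation of 0.01. That value was assumed and not estimated from these libraries, so the very small p-values of this version treat genes as nearly independent. Benjamini-Hochberg adjustment was over the 17 lists with more than 1 tested gene. The 6 lists chosen after the values were seen were adjusted apart, over those 6 alone. Camera with an estimated correlation called 0 of the 8 lists that the preset value called. That version rests on the 2 residual degrees of freedom, so it has little power here and a list that fails it is not shown to be unmoved. Fry, which asks whether the genes of a list move one way on balance, called 10 lists. Before the data were examined, 18 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule names TP53, MDM2, CDKN1A and ID1 to ID4, the 8 largest and 8 smallest log2 fold changes among called genes with a symbol, a mean of at least 5 TPM and groups that do not overlap, and for each list up to 4 called members with the largest absolute change, or 2 members of highest TPM where none was called. Other members are named only where they account for a count or were chosen after their values were seen, as the text then says.

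The procedure was tested on simulated data for Nutlin-3 against DMSO over 13692 genes. With 200 genes changed, 4.76%, 29.7% and 57.1% of changes of 0.5, 1 and 2 log2 units were recovered, and 1 of 62 calls was an unchanged gene. With 4108 genes changed, 52.6%, 80.9% and 94.8% were recovered, and 125 of 3248 calls (3.85%) were unchanged genes. With no change, 0 genes were called. Each setting was a single draw with independent errors per gene and with rises and falls equally likely. The real data differ in this, so these shares are not error rates of the calls below.

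Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean of 5 TPM, rescaling by median-of-ratios size factors, no mean-variance trend, the replicate number as a block, a minimum fold change of 1.2 (treat) and leaving out each library in turn. TPM recomputed without the cytosolic ribosomal protein genes was added after the data had been seen. Exons of 31 of the 68 named genes share bases with another annotated gene, on the same or the opposite strand. In AC025423.2, PLAU, CCNE2, DDIT4, IRF1, XPC and CD68 at least 20% of the exon bases are shared with 1 such gene, and the values of these 7 are uncertain to that extent. Overlaps, Fisher's exact tests and figures were computed in Python 3.11.15 with scipy 1.17.1.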

Results

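Gene expression was measured by paired-end sequencing of total RNA from MCF7 cells, a human breast cancer line of luminal type that carries wild-type p53. Cells received the vehicle DMSO or 10 µM Nutlin-3 for 8 h, with 2 libraries per group. Nutlin-3 blocks the binding of p53 by MDM2, the ubiquitin ligase that keeps p53 low, so that p53 accumulates. The title of the series names ID3 as a p53 target gene, and the comparison asks which transcripts, ID3 among them, changed when p53 was released from MDM2. Values were in TPM, the length-scaled abundance of a gene's transcripts within its library, for 37247 genes, and each library summed to 1000000, so the sequencing depth is unknown. In the DMSO libraries 13436 and 13356 genes reached 1 TPM, and in the Nutlin-3 libraries 13702 and 13698. Across the tested genes, the log2 values of the DMSO libraries had a Pearson r of 0.978 and those of the Nutlin-3 libraries 0.975, where genes are not independent replicates. Values below are the mean ± SD of n = 2 libraries, fold changes in log2 are differences of log2(TPM + 1), which understates the change of low genes, and adjusted p-values are from limma with Benjamini-Hochberg adjustment. The sources used here do not say that the libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera p-values with the preset correlation compare the genes of a list with other genes, and depend on that assumed correlation.

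Within 8 h Nutlin-3 raised most genes of the p53 target lists, by up to 6.23 log2 units, and lowered 36 of 40 genes of DNA replication and G1/S and 35 of 35 genes of G2/M. With an estimated correlation none of these lists passed against other genes (camera adjusted p from 0.053 to 0.15). That version of camera rests on 2 residual degrees of freedom and has little power here, so it does not decide whether the lists moved. Among called genes with a mean of at least 5 TPM, the largest increases in log2(TPM + 1) were in GDF15 and CDKN1A. GDF15 encodes a secreted stress cytokine (14.0 ± 2.04 to 1119 ± 92.5 TPM) and CDKN1A the cyclin-dependent kinase inhibitor p21 (75.4 ± 4.81 to 5111 ± 170.4 TPM). By the ratio of mean TPM, PRODH rose more than GDF15 (164.6-fold against 80.0-fold). The largest decreases in log2(TPM + 1) among these called genes were in UHRF1, ZNF367 and PLK1. UHRF1 helps to copy DNA methylation to newly made DNA (44.4 ± 0.789 to 1.97 ± 0.426 TPM). ZNF367 fell from 19.7 ± 1.01 to 0.703 ± 0.365 TPM and PLK1, a mitotic kinase, from 188 ± 3.70 to 16.5 ± 0.224 TPM. By the ratio of mean TPM, FAM111B fell more than UHRF1 (36.8-fold against 22.5-fold). Of 13692 genes with a mean of at least 1 TPM, 4515 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 1460 of them higher and 3055 lower with Nutlin-3. Among these, 632 were higher and 714 lower by at least 1 log2 unit. In all 4515 called genes both Nutlin-3 libraries lay on the same side of both DMSO libraries. With 2 libraries per group a call nearly requires this, so it adds no support. The same held for 68.6% of the tested genes against 33.3% by chance. That chance value assumes no shift common to all genes, and these values were not rescaled. The size factors were 1.06 and 1.04 for DMSO against 0.952 and 0.955 for Nutlin-3, so the excess is not a count of genes that responded. The median change of all tested genes was -0.11 log2 units, so a call of that size is no change relative to the median gene. After rescaling by median-of-ratios size factors, which moved this median to 0.02, 1988 genes were higher and 2037 lower, or 49.4 higher genes per 100 calls in place of 32.3. The counts fell with fewer libraries, to 545 higher and 762 lower without DMSO replicate 1, 564 and 899 without DMSO replicate 2, 655 and 1374 without Nutlin-3 replicate 1, and 666 and 1530 without Nutlin-3 replicate 2.

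**Figure D1:**
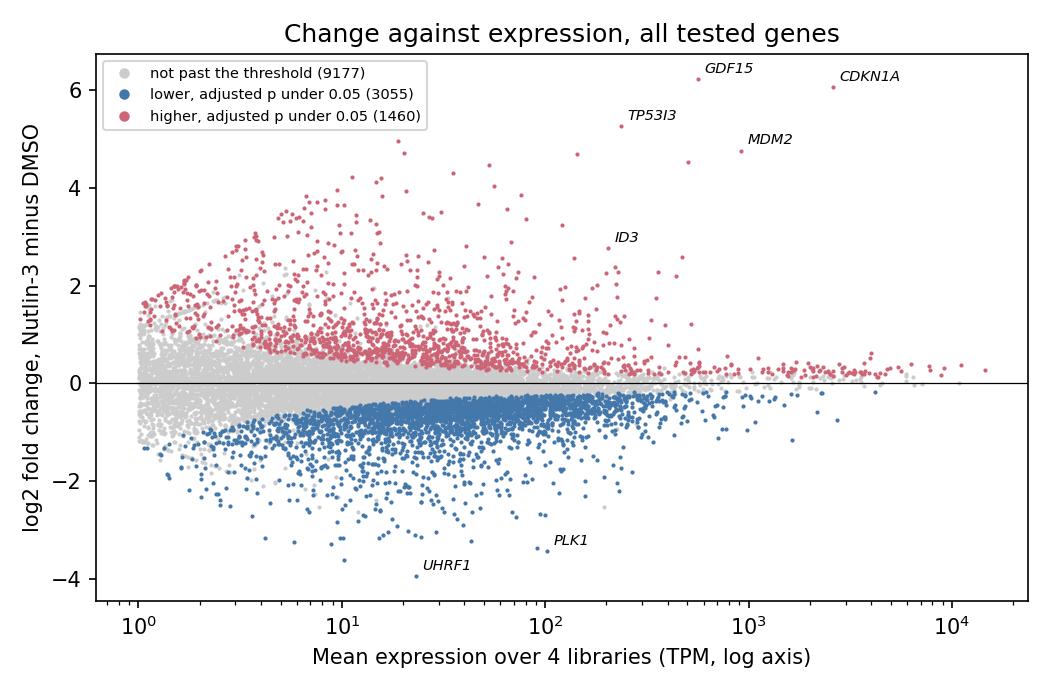
Change of each of the 13692 tested genes (vertical axis, log2 fold change, Nutlin-3 minus DMSO) against its mean TPM over the 4 libraries (horizontal log axis). Red points mark the 1460 genes higher and blue points the 3055 genes lower at an adjusted p under 0.05, and CDKN1A stands at 6.07 log2 units and UHRF1 at -3.94.

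ID3, which encodes a helix-loop-helix protein that binds E proteins and keeps them off DNA, rose 6.95-fold, from 51.4 ± 0.349 to 357 ± 14.0 TPM. Its log2 fold change was 2.77 with a standard error of 0.0643 (limma, Benjamini-Hochberg adjusted p = 6.2e-05 over all tested genes, and 1.6e-07 over the 4 ID genes alone). The gene (ENSG00000117318.8) lies on the minus strand of chromosome 1 at 23557918 to 23559794 in GRCh38. Its family members did not rise. ID1 fell from 60.8 ± 3.57 to 43.1 ± 0.0847 TPM (log2 fold change -0.48, limma with Benjamini-Hochberg adjusted p = 0.011), which was no longer past the threshold without DMSO replicate 1 (-0.54, adjusted p = 0.066), DMSO replicate 2 (-0.42, 0.091), Nutlin-3 replicate 1 (-0.48, 0.067) or Nutlin-3 replicate 2 (-0.49, 0.065). Nor did it pass with a minimum fold change of 1.2 (adjusted p = 0.10). ID2 went from 45.9 ± 2.51 to 42.2 ± 11.7 TPM (log2 fold change -0.14) and ID4 from 6.69 ± 0.819 to 4.58 ± 0.417 TPM (-0.46), and neither passed the test (limma, Benjamini-Hochberg adjusted p = 0.6 and 0.11); without Nutlin-3 replicate 1 the ID2 value was 0.13. Among the 13 tested genes of the list of ID genes and the response to bone morphogenetic proteins (BMP) and TGF-beta, 2 rose and 5 fell, and 2 rose and 6 fell when adjusted over the list alone. SERPINE1, which encodes the plasminogen activator inhibitor PAI-1, was the other riser (0.261 ± 0.215 to 8.99 ± 0.347 TPM). The falling genes included the ligand gene BMP4 (16.2 ± 5.21 to 4.49 ± 0.660 TPM) and SMAD6, an inhibitor of BMP signalling (11.7 ± 0.517 to 3.21 ± 0.119 TPM). BMP4 did not pass without DMSO replicate 1 (log2 fold change -1.30), Nutlin-3 replicate 1 (-1.74) or Nutlin-3 replicate 2 (-1.49). The list had a median log2 fold change of -0.37 and did not move against other genes (camera adjusted p = 0.49). After rescaling 2 members rose and 4 fell.

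**Figure D2:**
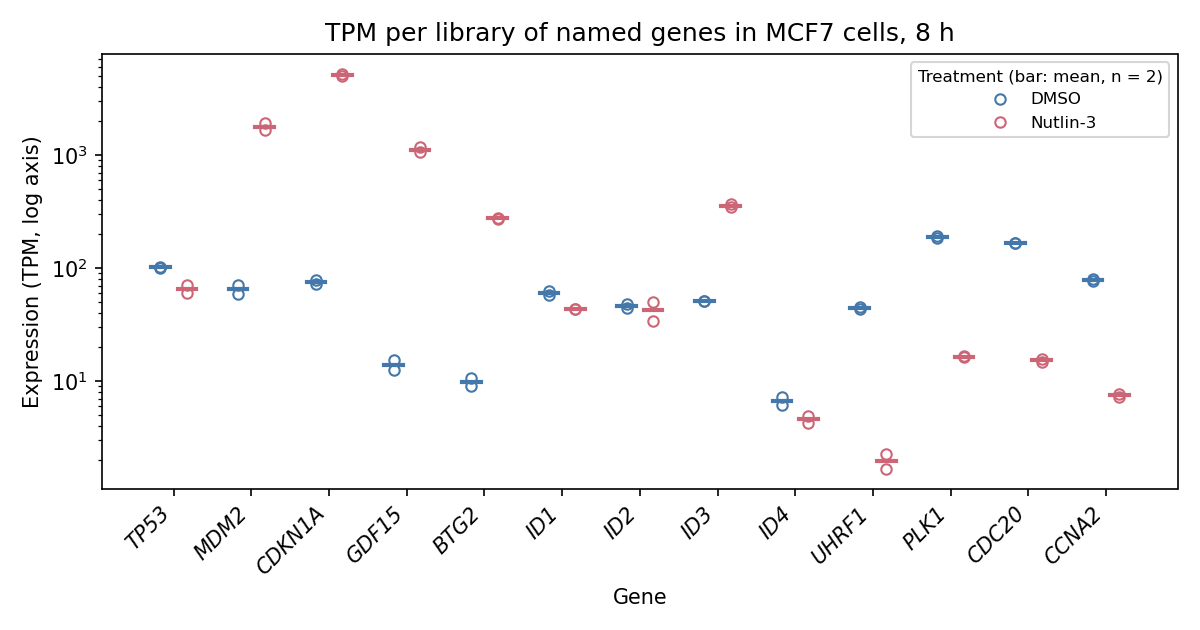
TPM of 13 genes (vertical log axis) in each library of MCF7 cells after 8 h, with 1 open circle per library and a bar at the mean of n = 2 for DMSO (blue) and Nutlin-3 (red). ID3 lies near 51.4 TPM in DMSO and 357 TPM in Nutlin-3, while ID1, ID2 and ID4 show no rise.

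The p53 mRNA itself did not rise. TP53 fell from 101 ± 0.599 to 65.1 ± 7.83 TPM (log2 fold change -0.64, limma with Benjamini-Hochberg adjusted p = 0.0076), a call that ended without DMSO replicate 1 (-0.63, adjusted p = 0.078) or DMSO replicate 2 (-0.64, 0.072). The genes of p53 feedback and cell cycle arrest rose together. Of 20 measured members 18 were higher and 0 lower, also when adjusted over the list alone, and RCHY1 and TRIM22 did not pass. MDM2 (ENSG00000135679.23, chromosome 12, 68808176 to 68850686 in GRCh38) rose 27.5-fold from 64.8 ± 7.53 to 1779.6 ± 173 TPM and CDKN1A (ENSG00000124762.13, chromosome 6, 36676460 to 36687339) rose 67.8-fold, with log2 fold changes of 4.76 (SE 0.105) and 6.07 (SE 0.0614; limma, Benjamini-Hochberg adjusted p = 5.5e-05 and 6.1e-06). BTG2, an antiproliferative gene, rose 28.2-fold (9.82 ± 1.10 to 277 ± 4.65 TPM). The pseudogene AC025423.2, also among the 8 largest increases, lies wholly inside MDM2 exons on the same strand and rose by 4.52 log2 units, so position alone cannot tell its reads from those of MDM2. The list had a median of 1.88 (camera adjusted p = 1.0e-19; adjusted p = 0.053 with an estimated correlation).

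Apoptosis genes among the p53 targets were also higher, in 16 of 18 tested members. TP53I3, a quinone oxidoreductase gene, rose 41.5-fold (11.1 ± 0.773 to 460.3 ± 14.3 TPM), the death receptor gene FAS 13.8-fold (4.15 ± 0.411 to 57.4 ± 5.73 TPM), SPATA18, which acts in mitochondrial quality control, 13.1-fold (3.81 ± 0.611 to 49.9 ± 0.186 TPM) and BBC3, which encodes the BH3-only protein PUMA, 7.82-fold (15.3 ± 0.420 to 119.8 ± 8.56 TPM). BID was lower, at -0.62 log2 units, and CASP8 did not pass; the counts were the same when adjusted over the list alone. The median was 1.99 (camera adjusted p = 9.9e-16; adjusted p = 0.053 with an estimated correlation). Of the 10 p53 targets of DNA repair and nucleotide supply, 7 were higher, led by DDB2 (68.3 ± 7.06 to 328 ± 10.3 TPM) and XPC (31.4 ± 4.87 to 144 ± 6.08 TPM), which recognise UV damage, the translesion polymerase gene POLH (7.81 ± 0.557 to 39.1 ± 0.591 TPM) and the ribonucleotide reductase subunit gene RRM2B (25.7 ± 3.29 to 119 ± 13.6 TPM). FANCC and PCNA were lower by the test, at -0.46 and -0.26, and after rescaling neither passed. The counts were unchanged when adjusted over the list alone. The list's median was 1.11 (camera adjusted p = 0.00015; adjusted p = 0.15 with an estimated correlation). In the list of p53 targets in metabolism and antioxidant defence 16 of 17 members rose, over all genes and adjusted over the list alone, and LPIN1 did not pass except after rescaling. Examples were the sestrin gene SESN1 (9.27 ± 0.137 to 121 ± 13.5 TPM), the ferredoxin reductase gene FDXR (22.2 ± 1.37 to 218 ± 3.51 TPM), the ceramidase gene ACER2 (2.97 ± 0.311 to 27.9 ± 0.0852 TPM) and the potassium-chloride cotransporter gene SLC12A4 (0.695 ± 7.4e-05 to 30.3 ± 5.44 TPM). This list had a median of 1.5 (camera adjusted p = 3.5e-16; adjusted p = 0.053 with an estimated correlation). Beyond the lists, PRODH, which encodes proline dehydrogenase (0.228 ± 0.0566 to 37.5 ± 9.61 TPM), and GABBR2, a GABA-B receptor subunit gene (0.616 ± 0.578 to 40 ± 4.90 TPM), were among the 8 largest increases.

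Genes of the cell division cycle fell. All 35 genes of the G2/M list were lower with Nutlin-3, over all genes and adjusted over the list alone, with log2 fold changes from -3.43 to -0.87. PLK1 fell 11.4-fold, CDC20, an activator of the anaphase-promoting complex, 10.9-fold (167 ± 0.0820 to 15.3 ± 0.645 TPM), the cyclin gene CCNA2 10.5-fold (78.5 ± 1.67 to 7.47 ± 0.344 TPM) and CENPA, the centromeric histone variant gene, 12.4-fold (28.2 ± 0.712 to 2.28 ± 0.453 TPM). The median was -2.20 (camera adjusted p = 1.4e-21; adjusted p = 0.12 with an estimated correlation). Of the 40 genes of DNA replication and G1/S, 36 fell and 0 rose, while TYMS, LIG1, GINS4 and POLE2 did not pass. Adjusted over the list alone, 1 rose and 36 fell, and after rescaling 2 rose and 36 fell. Besides UHRF1, the largest falls in log2(TPM + 1) were in the cyclin gene CCNE2 (19.0 ± 2.33 to 1.31 ± 0.844 TPM) and the replication initiation gene MCM10 (44.6 ± 3.63 to 4.28 ± 1.75 TPM). DTL, a substrate receptor of the CUL4 ubiquitin ligase, came next (41.7 ± 5.98 to 3.94 ± 0.137 TPM). The median was -1.77 (camera adjusted p = 1.0e-16; adjusted p = 0.053 with an estimated correlation). WDR76 (16.8 ± 0.919 to 0.844 ± 0.268 TPM) and FAM111B (11.4 ± 0.0759 to 0.308 ± 0.0391 TPM) were also among the 8 largest decreases.

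**Figure D3:**
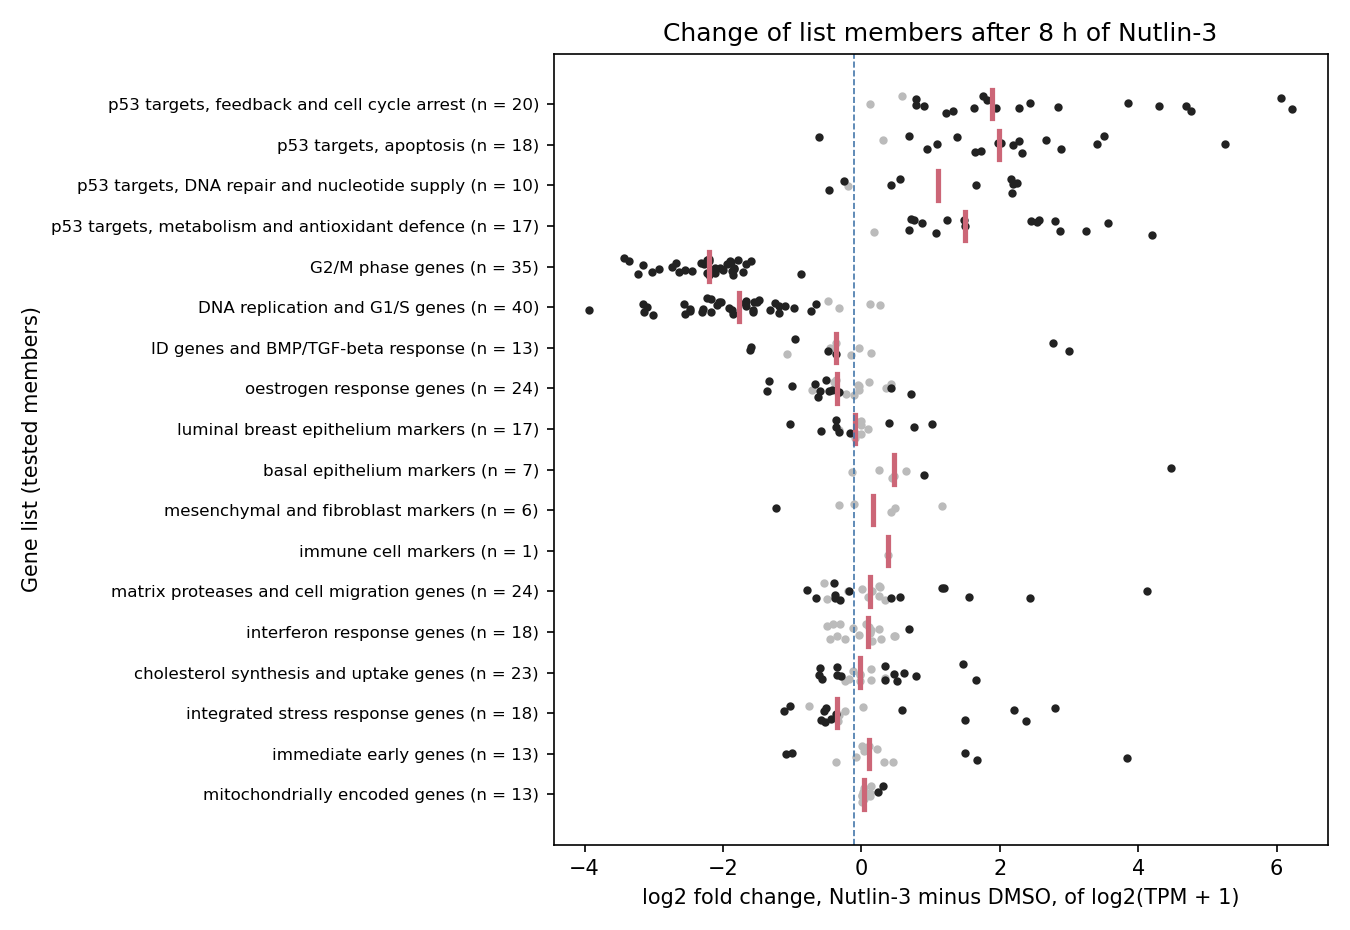
Log2 fold change (horizontal axis, Nutlin-3 minus DMSO) of the tested members of each of 18 gene lists, with black points for members at an adjusted p under 0.05, grey points for the others and a red bar at the list's median. The dashed line marks the median of all tested genes, -0.11, and the medians of the p53 target lists (1.11 to 1.99) lie to its right and those of the G2/M and G1/S lists (-2.20 and -1.77) to its left.

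Oestrogen response and luminal genes moved in both directions. Of 24 tested oestrogen response genes 2 were higher and 10 lower, 3 and 11 adjusted over the list alone, and 3 and 6 after rescaling. MYB, a transcription factor gene, fell (19.9 ± 0.412 to 7.31 ± 1.19 TPM), as did STC2 (28.7 ± 3.79 to 10.8 ± 4.17 TPM) and EGR3 (3.10 ± 0.269 to 1.04 ± 0.0571 TPM), and XBP1, a regulator of the unfolded protein response, rose (429 ± 0.798 to 703 ± 32.5 TPM). The list had a median of -0.35 and did not pass against other genes (camera adjusted p = 0.19). Among 17 luminal breast epithelium markers 3 were higher and 6 lower, 3 and 7 adjusted over the list alone, and 5 and 3 after rescaling. TFAP2C (131 ± 0.972 to 63.5 ± 3.08 TPM) and the adhesion gene EPCAM (166 ± 2.78 to 110.4 ± 10.4 TPM) fell and the tight junction gene CLDN4 (108 ± 1.57 to 219.7 ± 13.5 TPM) and the transcription factor gene ELF3 (113 ± 1.01 to 192 ± 6.06 TPM) rose. The luminal median was -0.09 and turned to 0.05 after rescaling (camera adjusted p = 0.75 and 0.53). The oestrogen receptor gene ESR1, chosen after its values were seen, went from 349 ± 11.7 to 279 ± 20.7 TPM (log2 fold change -0.32, limma with Benjamini-Hochberg adjusted p = 0.021, and -0.18 with 0.11 after rescaling). The calls of MYB (-1.32 without DMSO replicate 1), STC2 (-1.24 and -1.50 without DMSO replicate 1 or 2, -1.0 without Nutlin-3 replicate 2), EPCAM (-0.57 and -0.61 without DMSO replicate 1 or 2) and EGR3 (-0.93 to -1.07 without any 1 of the 4 libraries) ended with fewer libraries. With all libraries, STC2 did not pass with no filter on low values (adjusted p = 0.056). EGR3 did not pass with no filter (0.053), the replicate number as a block (0.059) or a minimum fold change of 1.2 (0.089).

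Of 12 basal epithelium markers 7 were tested and 2 rose, 3 adjusted over the list alone, and 3 after rescaling. ACTA2, the smooth muscle actin gene, rose from 3.69 ± 0.981 to 102 ± 1.88 TPM, and the laminin gene LAMB3 from 2.21 ± 0.00858 to 5.03 ± 0.469 TPM, whose call ended without any 1 of the 4 libraries (0.83 to 0.98). The LAMB3 call also ended with no filter on low values (adjusted p = 0.067) and with a minimum fold change of 1.2 (0.072). Exons of ACTA2 and FAS share 380 bases on opposite strands, and whether strand was used in counting is not given in the sources used here. The basal keratin genes KRT5, KRT14 and KRT6A were listed at 0 in all 4 libraries. The basal list had a median of 0.47 (camera adjusted p = 0.013; adjusted p = 0.25 with an estimated correlation; 0.082 with no filter on low values). Of 18 mesenchymal and fibroblast markers 6 were tested, 0 rose, and SNAI1, which encodes a repressor of E-cadherin, fell (3.15 ± 0.769 to 0.758 ± 0.328 TPM; 0 fell adjusted over the list alone), a call that ended without any 1 of the 4 libraries (-1.43 to -1.05). It also ended with no filter on low values (adjusted p = 0.061), with the replicate number as a block (0.0504) and with a minimum fold change of 1.2 (0.073). The mesenchymal and fibroblast median was 0.16 (camera adjusted p = 0.62), and -0.01 with no filter on low values. Of 11 immune cell markers in the table only CD68 was tested, at 1.37 ± 0.0342 to 2.08 ± 0.180 TPM, and it did not pass over all genes or adjusted over the list alone.

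Genes of matrix proteolysis and cell migration, the process the series title links to ID3 in lung cancer cells, also went both ways: 7 of 24 tested were higher and 7 lower, 7 and 8 adjusted over the list alone, and 8 and 3 after rescaling. SERPINB5, which encodes the serpin maspin, rose from 0.714 ± 0.232 to 28.7 ± 0.135 TPM, the urokinase gene PLAU from 0.848 ± 0.00826 to 8.99 ± 0.485 TPM, the tetraspanin gene CD82 from 14.6 ± 4.93 to 43.9 ± 0.0628 TPM and the GTPase gene RHOC from 234 ± 10.8 to 537 ± 3.50 TPM. CD82 did not pass without Nutlin-3 replicate 1 or Nutlin-3 replicate 2 (log2 fold change 1.56 in both cases), and 31.1% of the exon bases of PLAU overlap C10orf55 on the other strand. The median was 0.12 and the list did not pass against other genes (camera adjusted p = 0.12), and with a minimum mean of 5 TPM the median was -0.02.

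Stress and signalling lists changed in part. Of 18 genes of the integrated stress response 5 rose and 8 fell (5 and 9 adjusted over the list alone, 5 and 6 after rescaling). The risers included SESN2 (9.46 ± 0.80 to 72.0 ± 1.85 TPM), also in the metabolism list of p53 targets, DDIT4, an inhibitor of mTORC1 (69.9 ± 1.0 to 369.5 ± 21.6 TPM), NUPR1 (10.1 ± 1.21 to 50.1 ± 3.35 TPM) and ATF3 (8.0 ± 2.62 to 23.9 ± 1.27 TPM). The list's median was -0.35, its mean 0.15 and its test direction downward (camera adjusted p = 0.75). Of 13 tested immediate early genes 3 rose and 2 fell, 4 and 2 adjusted over the list alone, and 5 and 2 after rescaling. IER3 of this list, in the region of chromosome 6 with many low values, was listed at 0 to 0.407 TPM and not tested. FOSL1 (1.19 ± 0.337 to 30.4 ± 5.31 TPM) and FOS (2.30 ± 0.607 to 9.64 ± 2.67 TPM), which encode subunits of the transcription factor AP-1, rose with ATF3, and KLF6 fell (28.7 ± 0.228 to 12.9 ± 0.888 TPM). This list's median was 0.10 (camera adjusted p = 0.12), 0.34 without Nutlin-3 replicate 1 (0.048), -0.01 without Nutlin-3 replicate 2 (0.42) and 0.10 with a minimum mean of 5 TPM (0.041). FOS did not pass without DMSO replicate 1 (1.87), DMSO replicate 2 (1.49) or Nutlin-3 replicate 2 (1.42), nor ATF3 without Nutlin-3 replicate 1 (1.44) or Nutlin-3 replicate 2 (1.55). Of 18 tested interferon response genes, IRF1 was higher (5.19 ± 0.422 to 9.02 ± 1.46 TPM) and 0 were lower; adjusted over the list alone 0 passed, and after rescaling 2 were higher. The IRF1 call ended without any 1 of the 4 libraries (0.54 to 0.84). It also ended with no filter on low values (adjusted p = 0.10), with the replicate number as a block (0.056) and with a minimum fold change of 1.2 (0.14). The list's median was 0.09 (camera adjusted p = 0.38), or -0.01 without DMSO replicate 1.

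Of 23 tested genes of cholesterol synthesis and uptake 8 rose and 6 fell, over all genes and adjusted over the list alone, and 8 and 3 after rescaling. TM7SF2 (18.3 ± 2.02 to 59.6 ± 6.81 TPM), HSD17B7 (16.5 ± 1.63 to 47.7 ± 5.67 TPM) and SC5D (23.8 ± 0.150 to 42.2 ± 4.06 TPM), which encode enzymes of the later steps, and HMGCR (38.8 ± 1.36 to 60.2 ± 4.30 TPM), the gene of the rate-limiting enzyme, rose. HMGCR and SC5D did not pass without DMSO replicate 1 (0.59 and 0.80) or DMSO replicate 2 (0.66 and 0.79). The list's median was -0.01, its mean 0.15 and its test direction upward (camera adjusted p = 0.18), and the median was 0.13 after rescaling. The median was also above 0 without DMSO replicate 2 (0.039), Nutlin-3 replicate 1 (0.032) or Nutlin-3 replicate 2 (0.0004). Of the 13 mitochondrially encoded genes, MT-ND3 (8098 ± 9.11 to 10089.5 ± 1389 TPM) and MT-ND6 (2256 ± 141 to 2673 ± 167 TPM) were higher and 0 lower, 0 passed when adjusted over the list alone, and 6 were higher after rescaling. The list's median was 0.03 (camera adjusted p = 0.032; adjusted p = 0.63 with an estimated correlation), 0.02 without DMSO replicate 2 (0.15) and -0.0035 without Nutlin-3 replicate 1 (0.30). MT-ND3 did not pass without DMSO replicate 1 or 2 (0.31 in both cases) or Nutlin-3 replicate 1 (0.17), nor MT-ND6 without any 1 of the 4 libraries (0.18 to 0.31). With all libraries, MT-ND3 and MT-ND6 did not pass with no filter on low values (adjusted p = 0.17 and 0.13), without the mean-variance trend (0.17 and 0.18) or with a minimum fold change of 1.2 (0.65 and 0.96). Mitochondrial transcripts made up 5.56% and 5.32% of TPM in the DMSO libraries and 6.19% and 5.50% in the Nutlin-3 libraries.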

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

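The alternative without ribosomal protein genes was chosen after the data were seen. The log2 fold change of ID3 lay between 2.73 and 2.92 over 13 alternatives, with limma adjusted p-values from 1.1e-05 to 0.026. Of 865 comparisons of 67 named genes with an alternative, 796 kept the direction and the side of the threshold, 68 no longer passed and 1 changed sign (ID2, from -0.42 to 0.13 over the libraries left out in turn and never past the threshold). Most of the calls that ended did so with 1 library left out (15, 13, 11 and 11 named genes without DMSO replicate 1, DMSO replicate 2, Nutlin-3 replicate 1 and Nutlin-3 replicate 2, ID2 included), which leaves 1 library in a group that is assumed to vary like the other group. With all libraries, calls ended for STC2, EGR3, LAMB3, SNAI1, IRF1, MT-ND3 and MT-ND6 with no filter on low values, for MT-ND3 and MT-ND6 without the mean-variance trend, for EGR3, SNAI1 and IRF1 with the replicate block, and for ID1, EGR3, LAMB3, SNAI1, IRF1, MT-ND3 and MT-ND6 with a minimum fold change of 1.2.

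With a minimum fold change of 1.2, 767 genes were higher and 1415 lower. Leaving out 1 library gave 545 to 666 genes higher and 762 to 1530 lower, and the smaller counts go with fewer samples. For the following the cause was not tested. Without a filter on low values the basal epithelium markers (median 0.45, adjusted p = 0.082) and the mitochondrially encoded genes (0.035, 0.086) no longer passed and the mesenchymal and fibroblast markers changed sign (-0.015). With a minimum mean of 5 TPM the matrix proteases and cell migration genes changed sign (-0.016) and the immediate early genes passed (0.10, 0.041). Rescaling changed the sign of the luminal breast epithelium markers (0.051) and of the cholesterol synthesis and uptake genes (0.13), which also turned without ribosomal protein genes in the total (0.064). Without the mean-variance trend the mitochondrially encoded genes did not pass (0.035, 0.12). With 1 library left out in turn, medians kept their sign for the luminal (-0.16 to -0.020), basal (0.38 to 0.72) and mesenchymal and fibroblast markers (0.087 to 0.25). Over the libraries left out in turn, medians ranged from -0.0093 to 0.029 for interferon response genes, -0.0078 to 0.039 for cholesterol synthesis and uptake genes, -0.0035 to 0.13 for mitochondrially encoded genes and -0.014 to 0.34 for immediate early genes. With an estimated correlation none of the 8 called lists passed, at unchanged medians: p53 targets, feedback and cell cycle arrest (1.88), p53 targets, apoptosis (1.99), p53 targets, metabolism and antioxidant defence (1.5) and DNA replication and G1/S genes (-1.77), each at an adjusted p of 0.053, then G2/M phase genes (-2.20, 0.12), p53 targets, DNA repair and nucleotide supply (1.11, 0.15), basal epithelium markers (0.47, 0.25) and mitochondrially encoded genes (0.035, 0.63). By fry the oestrogen response genes (-0.35, 0.0071), the matrix proteases and cell migration genes (0.12, 0.012) and the cholesterol synthesis and uptake genes (-0.013, 0.046) passed and the mitochondrially encoded genes did not (0.035, 0.48).

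The replicate numbers are shared by the groups, but same-numbered libraries did not deviate together (correlation of deviations across genes 0.020). With 2 libraries per group this cannot exclude a shared culture or day with a small effect, and the labels do not say whether there was one. With the replicate number as a block, 1370 genes were higher and 2858 lower, and 4025 of the main calls were kept in the same direction. TPM keeps no read depth, so what depth limits was not assessed.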

Other observations

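The ribosomal protein, translation factor, chaperone, repair and tubulin lists, the tests of the ribosomal protein pattern, the recomputed TPM, the test among genes of at least 20 TPM, the reasons for not relying on the ratios of 0.70 and 1.02 and the bound by which the overlap of pseudogenes was judged were chosen after the values were seen; the other tests were set before their results. Genes of homologous recombination and the Fanconi anaemia pathway, which repair double-strand breaks and crosslinks, were lower in 21 of 25 cases and higher in 0, before and after rescaling, with a median log2 fold change of -1.42 (camera adjusted p = 4.7e-09; adjusted p = 0.13 with an estimated correlation). Examples were EXO1 (18.3 ± 1.0 to 1.18 ± 0.355 TPM), RAD51 (46.7 ± 0.661 to 8.41 ± 3.10 TPM) and BRCA1 (21.2 ± 3.18 to 4.95 ± 0.255 TPM). Of 7 mismatch repair genes 3 fell, MSH6 (111 ± 5.10 to 22.1 ± 1.61 TPM) and MSH2 (45.5 ± 0.342 to 15.4 ± 1.78 TPM) most. PMS1 also fell, at -0.54 log2 units, and did not pass after rescaling. The camera p of the list was 0.038, and 0.046 adjusted over only the 6 lists chosen after the values were seen. Its camera adjusted p was 0.47 with an estimated correlation and 0.051 after rescaling, so the call lies at the edge of the threshold. Of 18 listed chaperone and chaperonin genes of the cytosol or, for HSPD1 and HSPE1, the mitochondria, 16 were tested. Of these 12 fell and 0 rose, and 10 fell after rescaling. The median was -0.45 (camera adjusted p = 1.2e-06, and 0.15 with an estimated correlation). HSPA1A and HSPA1B, in the region of chromosome 6 with many low values, were listed at 0 to 0.379 TPM and not tested. HSPA8, which encodes the constitutive Hsp70, fell from 2260.4 ± 49.1 to 1009.6 ± 14.3 TPM, and the chaperonin subunit gene CCT5 from 769.9 ± 10.0 to 456 ± 11.4 TPM. Tubulin genes split. Of 10 listed 9 were tested and 4 were lower, among them TUBA1B (3419 ± 9.96 to 2051 ± 14.0 TPM) and TUBA1C (1289 ± 28.8 to 664 ± 5.85 TPM). TUBA1A, TUBB3 and TUBB6 were higher (camera adjusted p = 0.39), and the counts higher and lower were the same after rescaling.

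More genes were lower than higher (3055 against 1460, or 2.09 lower genes per higher gene). Less power for rising genes as the only cause is argued against among the 6080 genes with a mean of at least 20 TPM. There 2111 genes were called lower and 722 higher, or 2.92 lower calls per higher call. Rises and falls of at least 1 log2 unit were called in 98.0% and 98.7% of cases. By the sign of the change alone, which involves no test, 4117 of these genes lay below 0 and 1963 above it, a ratio of 2.10 (1.95 to 2.16 with 1 library left out in turn). The ratio of calls, 2.92, exceeds this ratio of signs, and the shares called cover only changes of at least 1 unit. A part played by power among smaller changes therefore stays open, as does the whole question below 20 TPM. Over all tested genes 652 lay at least 1 log2 unit below the median change and 930 at least 1 unit above it, a ratio of 0.70. This met the bound set beforehand for less power, a ratio of at most 1, but of the excess of 1595 lower calls 1513 came from changes under 1 unit, which this ratio does not cover. A closed TPM total, in which gains of abundant transcripts lower all other values, cannot be told apart from a loss of many transcripts under Nutlin-3. Median-of-ratios rescaling left 1.02 lower genes per higher gene, which met the bound set beforehand for a closed total, at most 1.2, but it centres the changes whatever their cause. In TPM recomputed without the ribosomal protein genes 1646 genes were higher and 2433 lower, or 1.48 lower genes per higher gene, but this too scales all remaining genes of a library by 1 factor, so neither ratio decides. The TPM scale holds no measure of total RNA that would decide.

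Cytosolic ribosomal protein genes rose from 21.6% to 25.7% of TPM, with 58 of 76 higher and 0 lower (73 and 0 after rescaling), a median of 0.23 and camera adjusted p = 5.9e-24 (adjusted p = 0.15 with an estimated correlation). A loss confined to a few other abundant transcripts, which would raise all remaining values in a closed total, is argued against by the median of all other tested genes, -0.11. A loss of many other transcripts would lower that median too, and a passive rise of this kind cannot be told apart from a gain of ribosomal protein transcripts. Of the 13616 other tested genes 3337 (24.5%) rose by at least the ribosomal median, neither most of them nor next to none, and TPM holds no measure of total RNA. A shift in the values of short transcripts cannot be told apart from a change of these genes: 76 other genes matched for length and, less closely, for TPM (median of mean TPM 1259.9 against 2558.7) had a median of 0.073 (95% bootstrap interval -0.020 to 0.129), between 0 and the ribosomal value, with 21 higher and 16 lower. The values are also consistent with a rise of mRNAs that start with a 5' terminal oligopyrimidine tract, since 16 translation factors and related genes of that class, none of them coding for a ribosomal protein, had a median of 0.18. Their camera test in limma gave an adjusted p of 0.0082, and 0.15 with an estimated correlation. Of these 16 genes 6 were higher and 1 lower, and 9 and 0 after rescaling. Ribosomal protein genes have many near-identical pseudogenes, and how reads that match several places were counted is not given in the sources used here. A rise of the class is a hypothesis found and tested on the same 4 libraries.

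Among 903 tested pseudogenes 113 were higher and 53 lower. Overlap was sought only with tested, higher-called genes on the same strand that are not pseudogenes. Such overlap accounts for few of them, as 3 of the 113 (2.65%) overlapped the span of such a gene. Of the 790 others 8 did (1.01%, two-sided Fisher's exact test, p = 0.15), and 110 of the 113 had no such overlap. The bound set beforehand, a share no higher than among the others, was not met. It was replaced after the share was seen by one of more than 50% of called pseudogenes without an overlap. A pseudogene without one cannot take reads by overlap from the genes searched. Reads of overlapping noncoding RNAs, most of which the table does not hold, or of genes on the other strand stay open. One of the 3 is AC025423.2 within MDM2. Reads shared with a parent gene cannot be excluded: of 41 called pseudogenes with a tested parent, 12 (29.3%) had a parent called higher, against 70 of 345 (20.3%; two-sided Fisher's exact test, p = 0.22), and the number of such pairs and the unknown treatment of multiply mapped reads keep this open. No biological explanation was tested for this pattern.

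Some IDs without a symbol in the tables used here changed strongly. ENSG00000235030.3 was listed at 191 and 188 TPM in the DMSO libraries and 459 and 483 TPM in the Nutlin-3 libraries, and ENSG00000276536.4 at 224 and 219.7 TPM and 401 and 449.6 TPM. ENSG00000235941.5 went from 104 and 98.2 TPM to 28.3 TPM in both Nutlin-3 libraries, and ENSG00000215328.6 from 186 and 193 TPM to 48.2 and 64.4 TPM. In all, 117 of the 489 tested IDs without a symbol were called.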
